A study of Mus musculus with 36 samples.

How the data were processed

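RNA was measured in sorted mouse bone marrow monocytes, at day 0 in MCSF (BMM) or after culture to day 4 with MCSF and RANKL (OC). Per the labels' protocols, total RNA was extracted with a column kit and made into Illumina libraries. The labels give 36 samples in 12 groups of genotype, stage and Ly6C subset. The table used here had a column for 34 of them, so 10 groups had 3 libraries and 2 groups had 2, and the other 2 samples were not analysed here. Mice of both sexes were used per the series' design text. The labels do not say that replicates came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical. Serial numbers in the sample titles pair no libraries.

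The deposited values are on a log2 scale and already normalised. No source used here states the transform. The submitters' processing notes name CASAVA 1.8.4, bcl2fastq 2.17.1, HISAT2, DESeq2 and deepTools with build mm10, and give them no roles, so the counting, the annotation and the use of strand are not given in the sources used here. Across all 34 libraries the low values formed 1 ladder of steps, each step being 1 read divided by a factor of the library, with 3.90 for 0 reads. Fitted over 40 levels, the ladder missed the values by at most 0.00116 (root mean square). This gave relative depths of 0.573 to 1.416, a 2.47-fold range. The transform is flat near 0 reads, so differences of genes with few reads are understated. Total reads per library are unknown, and a value near 3.90 means not detected at this depth. All pairs of libraries within a group differed by more than sampling noise (chi-square per gene 2.33 to 8.14 over 32 pairs, on genes with 40 to 300 reads), so no library was a copy of another.

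The values were tested as deposited with limma 3.58.1 in R 4.3.3. A linear model with 12 group means was fitted to the 34 libraries, with a trended and robust variance prior and 22 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each comparison and called under 0.05. A gene was tested if its value was above 4.78, the 5th percentile of values above the minimum, in at least 3 libraries, which kept 38873 of 38942 genes. The comparisons were 6 of cKO against WT, 6 of OC against BMM, 12 between Ly6C subsets, 3 genotype by RANKL interactions and 2 genotype by subset interactions (F tests), 29 in all. The plan had assumed linear values of 36 samples with a pseudocount. Since the values were already logarithmic, none was added. The main design, the lists, the rule for named genes and the alternatives, except 3 added later, were chosen before the data were examined.

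Gene identifiers were matched to GENCODE M21 (38928 of 38942 matched, 38902 with the same symbol), from which coordinates, chromosomes and gene types were taken, on mm10. Genes with near-identical copies, such as Gvin1, replication-dependent histones, immunoglobulin constant regions, Mir6236 and the pseudogenes Rpl31-ps11 and Rps23-ps2, are uncertain, because counting could split or lose their reads. The same holds for genes with an antisense partner.

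A gene was named if it was called, its highest group mean was at least the median over tested genes (5.44) and its symbol was not a placeholder. In comparisons of 2 groups, the groups also had to not overlap in any library, a condition not set for the interactions. List members only had to be called. Up to 10 rises and 10 falls with the largest change were taken for genotype and stage comparisons, up to 6 for the others, and up to 4 called members per list. Irf8 was always named, and the text gives those genes in rank order, in part. The values of 1 list member are not reported here. Ly6c2 levels in the subset comparison, Xist, Ddx3y and the group levels of Ctsk, Acp5, Arg1, Birc5 and Rsad2 are given as values. Among 24 lists, those about monocyte biology were osteoclast differentiation and function, transcriptional repressors of osteoclastogenesis, MHC class II, type I interferon-stimulated genes, interferon-gamma-inducible GTPases and antigen processing, classical and non-classical monocyte markers, macrophage markers and inflammatory cytokines and chemokines. Other cells were covered by neutrophil, dendritic, B cell, T and NK cell, erythroid and megakaryocyte, mast cell, basophil and eosinophil, progenitor and stromal and osteoblast markers. Function and quality were covered by cell cycle, oxidative phosphorylation, glycolysis, V-ATPase and lysosome, immediate early and heat shock, mitochondrially encoded and sex-linked genes. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, adjusted over 576 tests (24 lists in 24 comparisons). Of these 336 were called and 222 also with the estimated correlation.

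The alternatives were no filter, a stricter filter (25th percentile, 32236 genes), median-of-ratios rescaling, quantile normalization, only the compared libraries, no trended or robust prior, sample weights, an estimated correlation, a further minimum of 1 on the log2 difference and each library left out in turn. Added after seeing the data were a filter of at least 10 reads in 3 libraries (21775 genes), protein-coding genes only (19775) and no genes on X and Y (37337). A count model and other pseudocounts, planned for count or linear values, did not apply. Data were simulated with independent normal noise at 1 pooled spread per gene, with changes planted only in genes of at least median mean. The real libraries differed in spread (sample weights 0.32 to 2.19), so performance on the real data may be overstated. Far fewer genes were changed than the real comparisons called, which makes the adjustment stricter, so recovery may be understated in that respect. In the simulated data limma recovered 42.6%, 81.8% and 97.3% of genes changed by 0.5, 1 and 2 in the cKO against WT comparison of Ly6Chi BMM (38873 genes, 9 unchanged genes called). It recovered 24.3%, 58.5% and 93.5% in Ly6Cneg OC (2 unchanged called). Recovery was 12.1%, 50% and 83.3% for the genotype by RANKL interaction in Ly6Chi cells (3 unchanged called) and 19%, 58% and 80.8% for the genotype by subset interaction in OC (6 unchanged called), so an interaction that was not called may still be present. Figures and tables were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.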

Results

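RNA sequencing was done on mouse bone marrow monocytes sorted by surface Ly6C, a protein that separates monocyte subsets, into Ly6C-high (Ly6Chi), Ly6C-intermediate (Ly6Cint) and Ly6C-negative (Ly6Cneg) cells. Cells came from wild-type (WT) mice and from mice labelled as a conditional knockout (cKO) of Irf8, a transcription factor of monocyte and dendritic cell development that represses osteoclast formation. Libraries represented sorted bone marrow monocytes at day 0 in MCSF (BMM) or osteoclasts (OC), bone-resorbing cells, after culture to day 4 in MCSF (20 ng/ml) with RANKL at 40 ng/ml. These 12 groups had 3 libraries each, except the WT Ly6Cneg groups at both stages, which had 2, giving 34 libraries. The remaining sample of each of those groups was not analysed here. The table held a log2-scale value for 38942 genes, with the lowest value at 0 reads. Relative depth differed 2.47-fold between libraries, from 0.573 to 1.416 times a common reference, and each library had reads on 23053 to 35171 genes. Correlations between libraries across genes were 0.950 to 0.988 within groups and 0.905 to 0.985 between groups. All differences below are on the log2 scale with the standard error of the limma fit, and each adjusted p is from limma or from its camera list test. A list is given with the members called over all genes, its median difference and its adjusted p. The number adjusted over the list alone is given where it differs. Unless an estimated correlation is named, the adjusted p of a list is from the preset correlation between genes. Such values may be too small where members change together, and their size does not measure evidence between animals or cultures. Of 336 list calls, 114 were lost with an estimated correlation.

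Irf8 (ENSMUSG00000041515, chromosome 8, 120736358 to 120756694, plus strand, mm10) went against the genotype label, since its gene total was higher in every library labelled cKO than in every WT library of the same subset and stage. At the BMM stage the means were 14.23 against 13.55 in Ly6Chi cells (difference 0.68 ± 0.08, adjusted p = 1.07e-08), 14.25 against 13.38 in Ly6Cint cells (0.87 ± 0.08, 2.94e-11) and 14.03 against 12.75 in Ly6Cneg cells (1.27 ± 0.09, 1.42e-13). At the OC stage they were 11.98 against 10.10 in Ly6Chi cells (1.88 ± 0.08, adjusted p = 1.12e-19), 11.84 against 10.76 in Ly6Cint cells (1.08 ± 0.08, 4.58e-13) and 13.47 against 11.89 in Ly6Cneg cells (1.58 ± 0.09, 8.21e-17). The exact two-sided permutation test gave p = 0.1 for 3 against 3 libraries and 0.2 for 3 against 2, the smallest these numbers allow. A gene total holds no reads per exon and cannot check the deletion of an exon, so cKO below is the name of a label and each direction is relative to it. Within WT cells, Irf8 fell from day 0 to day 4 with RANKL in Ly6Chi (-3.45 ± 0.08), Ly6Cint (-2.63 ± 0.08) and Ly6Cneg cells (-0.86 ± 0.10).

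**Figure D1:**
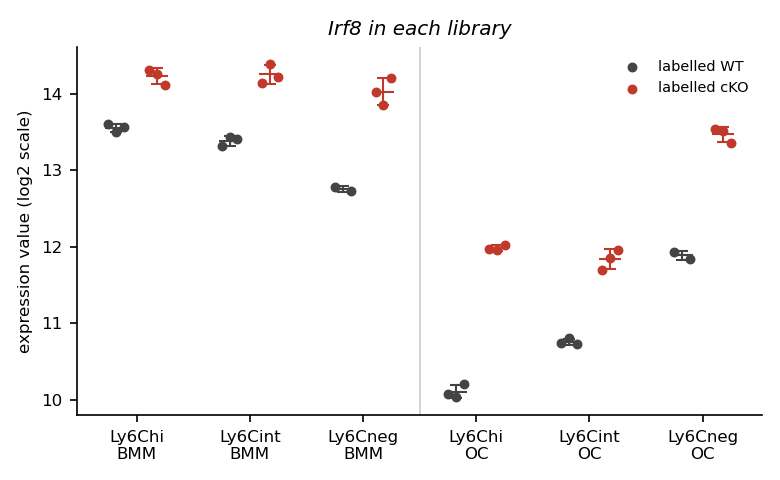
Irf8 value of each library on the log2 scale (vertical axis) by Ly6C subset and stage (horizontal axis), points for libraries and bars for mean ± SD, n = 3 per group and 2 in the WT Ly6Cneg groups. Libraries labelled cKO lie above the WT libraries in each of the 6 pairs of groups, with the widest gap (1.88) in Ly6Chi OC.

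Sex-linked genes divided the libraries in the same way as the genotype label. Xist, the X-inactivation RNA, had group means of 14.01 to 15.15 in WT and 12.24 to 13.66 in cKO, while the Y-linked helicase gene Ddx3y had 5.23 to 6.12 in WT and 10.53 to 10.77 in cKO. Of the 5 sex-linked genes listed, 4 were higher and 1 was lower in libraries labelled cKO in each of the 6 cKO against WT comparisons, with the same numbers when adjusted over the list alone. The mix of sexes and the genotype therefore cannot be separated in these comparisons. Genes on the X chromosome (1508 tested) were called in a smaller share than autosomal genes in each comparison, for example 28.4% against 40.1% in Ly6Cint BMM, where the gap was widest. Genes on the Y chromosome (28 tested) were called in a larger share in each, from 32.1% against 29.9% in Ly6Chi BMM to 53.6% against 23.3% in Ly6Cneg BMM. Most of these Y calls were higher in cKO, so the X share alone does not show that sex adds little.

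The first principal component held 35.2% of the variance and separated the stages, with group means from 24 to 105.3 in BMM and -95.1 to -8.8 in OC, and the second held 12.4%. Reads on olfactory receptor genes, which these cells do not use, differed between groups at similar depth, from a mean of 110.3 of 910 such genes detected in Ly6Chi OC to 753.3 in Ly6Cneg BMM, both labelled cKO (n = 3 each). The genotype comparisons ask which transcripts of each subset differ with the Irf8 label before and after RANKL. They called 11563, 15414 and 8966 genes in Ly6Chi, Ly6Cint and Ly6Cneg BMM, and 3056, 5490 and 6628 in the same subsets at the OC stage, of 38873 tested. Among the genes followed through the comparisons, C1qb lies on chromosome 4 (136880129 to 136886187, minus strand), Rsad2 on 12 (26442746 to 26456452, minus) and Birc5 on 11 (117849251 to 117855743, plus). The osteoclast genes Ctsk and Acp5 lie on chromosomes 3 (95499256 to 95509362, plus) and 9 (22126727 to 22135711, minus), Ccl2 on 11 (82035571 to 82037453, plus) and Col1a1 on 11 (94936224 to 94953042, plus).

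In Ly6Chi BMM, cells labelled cKO had far more proliferation transcripts and far less complement C1q than WT cells (n = 3 and 3). Ccl2, a monocyte chemoattractant, was 13.48 ± 0.40 (SD) in cKO and 7.77 ± 0.19 in WT (difference 5.71 ± 0.16, adjusted p = 2.18e-22), and its neighbour Ccl7 rose by 5.42 ± 0.23. Next among the autosomal rises came the serine synthesis enzyme Phgdh (4.36 ± 0.24), the replication factor Pclaf (4.20 ± 0.08), the neutrophil granule genes Camp (4.15 ± 0.34), Elane (4.07 ± 0.42) and Olfm4 (4.02 ± 0.25), and Birc5 (3.96 ± 0.13), a mitotic gene. C1qb fell from 16.29 ± 0.13 to 9.65 ± 0.26 (-6.64 ± 0.23, adjusted p = 2.2e-17), with C1qa (-6.42 ± 0.23), Hpgd (-6.03 ± 0.24), C1qc (-5.60 ± 0.19) and Ly86 (-5.48 ± 0.24) next. The interferon-inducible GTPase Gvin1 (-4.91 ± 1.34, adjusted p = 0.00608) was not called without WT BMM Ly6Chi replicate 1 (-3.39, 0.0674), nor with only the compared libraries or with sample weights. Calls were 5617 higher and 5946 lower, 4491 of them at least 2-fold, and numbered 7446 with only the compared libraries. Irf8 itself was 0.68 higher in these cKO libraries.

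All 27 cell cycle genes rose in Ly6Chi BMM labelled cKO (median 3.13, adjusted p = 1.69e-52), among them Rrm2 (3.68 ± 0.09), Ccna2 (3.65 ± 0.08) and Top2a (3.59 ± 0.11). All 26 type I interferon-stimulated genes fell (median -1.84, 2.4e-22), with Oasl2 at -3.43 ± 0.27 and Mx1 at -3.31 ± 0.20, as did 12 of 17 interferon-gamma-inducible genes (14 adjusted over the list alone, median -1.26, 7.79e-11), led by Gbp5 (-2.38 ± 0.12). Of 11 MHC class II genes 8 fell and 1 rose (median -1.99, 7.62e-11), with H2-Ab1 at -3.49 ± 0.12 and H2-Eb1 at -3.41 ± 0.12. Macrophage markers fell at 15 of 18 genes and rose at 1 (median -1.45, 9.7e-13). Neutrophil markers rose at 18 of 19 and fell at 1 (median 3.13, 1.92e-17), with Lcn2 at 3.87 ± 0.22. Of 11 classical monocyte markers 7 rose and 3 fell (median 2.46, adjusted p = 0.00115, and 0.0599 with an estimated correlation), led by Ly6c2, which encodes Ly6C itself (3.40 ± 0.19). The non-classical markers rose at 9 of 14 and fell at 4 (median 0.55, 0.0232). Glycolysis genes rose at 12 of 14 (13 adjusted over the list alone) and fell at 1 (median 0.87, 3.45e-08), and oxidative phosphorylation genes at 17 of 19 with 1 lower (median 0.73, 2.74e-08, adjusted p = 0.112 with an estimated correlation). Inflammatory cytokines rose at 10 of 19 (11 adjusted over the list alone) and fell at 4 (median 0.71, 0.00529, adjusted p = 0.0773 with an estimated correlation). Within WT BMM the classical markers were higher in Ly6Cint (median 2.55) and Ly6Cneg cells (1.45) than in Ly6Chi cells, and so was Ly6c2. WT and cKO Ly6Chi BMM may thus be unlike populations, which was not tested and limits every difference between them.

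Osteoclast genes in Ly6Chi BMM went both ways, 5 higher and 8 lower of 24 (median -0.13, adjusted p = 0.287). The collagenase Mmp14 (-3.41 ± 0.25) and the repressor gene Prdm1 (-3.00 ± 0.16) fell, while Mmp9 was higher by 1.53 ± 0.29. Of 7 transcriptional repressors of osteoclastogenesis, a list that holds Irf8, 3 rose (4 adjusted over the list alone) and 2 fell (adjusted p = 0.563). V-ATPase and lysosome genes rose at 6 of 22 (7 adjusted over the list alone) and fell at 10 (0.2). The immediate early and heat shock genes, which mark handling, rose at 5 of 12 and fell at 4 (5 adjusted over the list alone, 0.428). Among markers of other cells, dendritic cell genes fell at 5 of 12 (7 adjusted over the list alone, median -0.39, adjusted p = 0.0126, and 0.0843 with an estimated correlation), with Cd209a at -1.88 ± 0.25. No list call was made for B cells (0 higher and 1 lower of 13, adjusted p = 0.552), T and NK cells (2 and 0 of 12, 0.613) or erythroid and megakaryocyte genes (0 and 1 of 9, 0.464). Mast cell, basophil and eosinophil genes (2 and 0 of 9, 0.704), progenitor genes (4 and 3 of 10, 0.611, median -0.10 and mean 0.33) and stromal and osteoblast genes (1 and 1 of 11, 0.44) were not called as lists either. The mitochondrially encoded transcripts, an RNA quality list, had 3 higher of 12 (1 adjusted over the list alone, 0.45).

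In Ly6Cint BMM interferon-stimulated transcripts were far lower in cells labelled cKO than in WT cells (n = 3 and 3), and Irf8 was 0.87 higher in cKO. Rsad2, an antiviral enzyme, was 14.51 in WT and 7.95 in cKO (-6.56 ± 0.23, adjusted p = 4.79e-18), and Ifit3 (-6.42 ± 0.27) and Mx1 (-6.36 ± 0.20) followed C1qb (-6.58 ± 0.23). Gvin1 had the largest fall, -7.81 ± 1.34 (4.83e-05). Rises were led by granule enzymes of myeloid precursors, Mpo (5.68 ± 0.37, adjusted p = 5.63e-12), Elane (5.57 ± 0.42), Ctsg (5.28 ± 0.28) and Prtn3 (4.98 ± 0.35), beside Y-linked Eif2s3y (5.60 ± 0.13) and Ddx3y (5.50 ± 0.15). Ccl2 (4.77 ± 0.16) and Ccl7 (4.76 ± 0.23) came next. Fallen were 26 of 26 type I interferon genes (median -4.46, 6.54e-50), 17 of 17 interferon-gamma genes (-3.40, 7.9e-30), led by Iigp1 and Gbp2 (-5.21 ± 0.20 and -5.14 ± 0.14). MHC class II genes fell at 10 of 11 (-2.30, 5.86e-15, with 1 higher adjusted over the list alone). Macrophage markers fell at 16 of 18 and rose at 1 (-2.34, 2.03e-20), led by C1qc (-5.82 ± 0.19) and Axl (-5.66 ± 0.10), and dendritic markers fell at 10 of 12 (-1.01, 4.04e-07). All 27 cell cycle genes rose (1.83, 4.57e-31), with Birc5 at 2.62 ± 0.13. Neutrophil genes rose at 17 of 19 (18 adjusted over the list alone) and fell at 1 (1.68, 2.11e-09, adjusted p = 0.133 with an estimated correlation). Osteoclast genes went both ways, 11 higher (12 adjusted over the list alone) and 10 lower of 24, with a median of 0.34 and a mean of 0.00 (adjusted p = 0.33), and Ctsk, the osteoclast collagenase cathepsin K, rose by 2.33 ± 0.39. Calls were 9711 higher and 5703 lower, 63% higher against 51.5% under quantile normalization, which moved the median of all genes from 0.28 to 0.05. Protein-coding genes made up 6176 of the higher and 4707 of the lower calls. Olfactory receptor genes with reads were also more in cKO (543.7, against 344.7 in WT).

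In Ly6Cneg BMM (n = 3 cKO and 2 WT), where Irf8 was 1.27 higher, the fractalkine receptor gene Cx3cr1 was 12.70 ± 0.10 in cells labelled cKO and 8.02 ± 0.01 in WT (4.68 ± 0.09, adjusted p = 1.17e-30). Y-linked Ddx3y (5.28 ± 0.17), Eif2s3y (4.89 ± 0.15) and Uty (4.85 ± 0.29) rose more. Next rose Retnlg (4.58 ± 0.30), Ifi202b (4.06 ± 0.27) and the chemokine gene Cxcl14 (3.92 ± 0.10). Falls included the immunoglobulin genes Igha (-5.15 ± 0.60) and Ighg2b (-4.72 ± 0.57), the eosinophil-associated ribonuclease Rnase2a (-4.92 ± 0.22), the lectin Mgl2 (-4.64 ± 0.17), and the basophil protease Prss34 (-4.43 ± 0.52). Vcan (-4.02 ± 0.23), C1qb (-3.84 ± 0.26) and the arginase gene Arg1 (15.57 in WT, 11.75 in cKO, -3.82 ± 0.28) also fell. Gvin1 (-5.46 ± 1.5, 0.0103) was not called without WT BMM Ly6Cneg replicate 1 (-4.76, 0.101). MHC class II genes fell at 11 of 11 (median -2.10, adjusted p = 1.13e-25), led by their activator Ciita (-3.04 ± 0.16), and dendritic markers at 7 of 12 (-1.27, 2.12e-10). Mast cell, basophil and eosinophil markers fell at 7 of 9 (8 adjusted over the list alone, -2.07, 5.53e-11), with Cpa3 at -2.93 ± 0.44 and Prg2 at -2.87 ± 0.42. Classical markers fell at 5 of 11 and rose at 1 (-0.59, 3.88e-05), while inflammatory cytokines rose at 9 of 19 and fell at 1 (0.48, 9.35e-05), with Il1rn at 2.43 ± 0.14. Type I interferon genes, 3 higher and 6 lower of 26 (median 0.08, mean -0.03, adjusted p = 0.279), and cell cycle genes, 10 higher and 2 lower of 27 (11 and 4 adjusted over the list alone, median 0.11, 0.263), were not called as lists. Osteoclast genes rose at 11 of 24 (12 adjusted over the list alone) and fell at 5 (median 0.56, 0.165), with Mmp9 at 2.92 ± 0.33 and Acp5 at 1.90 ± 0.43, both not called with only the compared libraries. Olfactory receptor genes with reads were more in cKO (753.3, against 607 in WT), and protein-coding calls were 3583 higher and 3280 lower. Of the 8966 calls 59.2% were higher, against 46.7% under quantile normalization, which moved the median of all genes from 0.27 to 0.03, and calls numbered 4573 without WT BMM Ly6Cneg replicate 2, 5844 without replicate 1 and 4982 with only the compared libraries.

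In Ly6Chi OC (n = 3 and 3), where Irf8 was 1.88 higher in libraries labelled cKO, osteoclast genes did not differ as a list. Ctsk was 18.58 ± 0.03 (SD) in WT and 18.20 ± 0.09 in cKO, and 1 of 24 members was called (Ostm1, -0.21 ± 0.07), 0 when adjusted over the list alone (median -0.04, adjusted p = 0.891). The Ostm1 call was lost without any 1 of the 6 libraries of the comparison (-0.24 to -0.17). After the Y-linked Ddx3y (5.11 ± 0.15) and Eif2s3y (4.80 ± 0.13) rose Lad1 (4.62 ± 0.26, adjusted p = 1.37e-14), Y-linked Kdm5d and Uty, and the alcohol dehydrogenase Adh7 (4.02 ± 0.40). Pdpn, which encodes podoplanin, and C1qb fell most (-3.49 ± 0.31 and -3.49 ± 0.23), before Hgsnat (-2.80 ± 0.08), a lysosomal enzyme, Nol4 (-2.77 ± 0.38) and Gdf3 (-2.73 ± 0.22). Type I interferon genes, which had fallen at the BMM stage, rose at 20 of 26 (23 adjusted over the list alone, median 1.07, 2.09e-31), led by Rtp4 (1.74 ± 0.18) and Irf7 (1.65 ± 0.20). Interferon-gamma genes rose at 11 of 17 (13 adjusted over the list alone, 0.57, 2.31e-14). Cell cycle genes fell at 15 of 27 (22 adjusted over the list alone, -0.30, 1.44e-14). MHC class II genes fell at 8 of 11 with 2 higher (-0.85, 2.62e-07), and macrophage markers at 8 of 18 with 2 higher (3 adjusted over the list alone, -0.18, 1.04e-05). Classical markers rose at 3 of 11 (6 adjusted over the list alone, 0.54, 5.3e-07), led by the coagulation factor F13a1 (1.87 ± 0.17), and immediate early genes rose at 8 of 12 and fell at 2 (0.42, 6.41e-05), Egr1 by 1.91 ± 0.41. Neutrophil genes rose as a list with 1 of 19 called (2 adjusted over the list alone, 0.34, 0.00614, adjusted p = 0.512 with an estimated correlation). Calls were 1652 higher and 1404 lower, 753 at least 2-fold, and numbered 6535 with sample weights.

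In Ly6Cint OC (n = 3 and 3), with Irf8 1.08 higher in cKO, osteoclast genes rose in libraries labelled cKO at 14 of 24 members (17 adjusted over the list alone) and fell at 0 (median 0.61, adjusted p = 6.92e-13). Examples were the calcitonin receptor Calcr (1.5 ± 0.24), Car2 (1.08 ± 0.24), Siglec15 (0.98 ± 0.22) and Nfatc1, the main transcription factor of osteoclast formation (13.88 in WT, 14.78 in cKO, 0.90 ± 0.14). The repressors of osteoclastogenesis fell at 4 of 7 (5 adjusted over the list alone) with 1 higher, Irf8 (median -0.78, 2.91e-05), with Id3 at -2.34 ± 0.12. Neutrophil genes rose at 18 of 19 (1.89, 1.04e-29), with Ltf (4.05 ± 0.30) and S100a9 (3.89 ± 0.29), as did 8 of 11 classical markers (2.54, 1.74e-15), with F13a1 (3.96 ± 0.17). The phosphodiesterase Pde3a rose by 4.33 ± 0.30. C1qb (-4.49 ± 0.23, adjusted p = 3.26e-13), Pdpn (-4.01 ± 0.31), the efferocytosis receptor Axl (-3.83 ± 0.10), C1qa (-3.73 ± 0.23), C1qc (-3.69 ± 0.19) and langerin (Cd207, -3.55 ± 0.12) fell most. Cell cycle genes fell at 26 of 27 (27 adjusted over the list alone, -1.07, 5.78e-52). MHC class II genes fell at 8 of 11 (9 adjusted over the list alone) with 1 higher (-1.98, 7.99e-20), and macrophage markers at 12 of 18 with 2 higher (3 adjusted over the list alone, -0.82, 2.3e-17). Type I interferon genes fell at 12 of 26 (15 adjusted over the list alone, -0.42, 5.92e-10, adjusted p = 0.146 with an estimated correlation). Oxidative phosphorylation genes rose at 15 of 19 (18 adjusted over the list alone, 0.65, 1.72e-16). Calls were 3181 higher and 2309 lower, 1289 at least 2-fold, and numbered 9034 with sample weights.

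Of the 6 genotype comparisons, Ly6Cneg OC (n = 3 cKO and 2 WT) had the largest osteoclast median, with 23 of 24 genes higher in libraries labelled cKO (24 adjusted over the list alone, median 1.35, adjusted p = 9.71e-26), where Irf8 was 1.58 higher. Ctsk was 17.43 ± 0.13 (SD) in cKO and 14.65 ± 0.08 in WT, and Acp5, the tartrate-resistant acid phosphatase, 17.15 ± 0.15 and 14.33 ± 0.10 (2.83 ± 0.43). Calcr (3.46 ± 0.27), Siglec15 (3.18 ± 0.24) and the integrin Itgb3 (2.91 ± 0.26) rose more. All 27 cell cycle genes fell (-2.97, 9.07e-73), and Stmn1 (-4.14 ± 0.30), Ncapd2 (-3.87 ± 0.11), Top2a (-3.85 ± 0.12), Cenpf (-3.84 ± 0.17), Ccnb2 (-3.76 ± 0.09) and Ube2c (-3.73 ± 0.11) were the named falls. Collagen genes led the autosomal rises, Col1a1 by 5.17 ± 0.42 (13.06 in cKO, 7.89 in WT, adjusted p = 7.35e-10) and Col1a2 by 5.13 ± 0.30. The chemokine Cxcl2 (4.86 ± 0.15), Ccn2 (4.53 ± 0.48), fibronectin (Fn1, 4.46 ± 0.31) and Sparc (4.35 ± 0.36) followed. The stromal and osteoblast markers rose at 8 of 11 (1.71, 4.21e-07). Other cell lists moved as well. Neutrophil genes rose at 10 of 19 (1.39, 5.14e-09) and classical markers at 6 of 11 with 1 lower (1.23, 0.000854), with adjusted p = 0.143 and 0.0549 with an estimated correlation, and dendritic markers fell at 5 of 12 (2 higher and 7 lower adjusted over the list alone, -0.56, 0.0035). Inflammatory cytokines rose at 13 of 19 and fell at 1 (2 adjusted over the list alone, 1.19, 6.29e-16), with Cxcl1 (3.75 ± 0.25) and Tnf (2.58 ± 0.10), and 12 of 12 immediate early genes rose (1.38, 6.54e-17), Egr1 by 4.13 ± 0.46. Repressors of osteoclastogenesis rose at 4 of 7 (5 adjusted over the list alone) and fell at 1 (2 adjusted over the list alone, 0.55, 0.00222), with Id1 at 2.04 ± 0.20. V-ATPase and lysosome genes rose at 15 of 22 (16 adjusted over the list alone, 0.56, 8.63e-12) and non-classical markers at 12 of 14 with 2 lower (0.91, 3.6e-06). Interferon-gamma genes fell at 11 of 17 (13 adjusted over the list alone, -1.03, 4.67e-11), and MHC class II genes at 7 of 11 (8 adjusted over the list alone) with 1 higher (-0.57, 0.000274, adjusted p = 0.13 with an estimated correlation). Calls were 3705 higher and 2923 lower, 2263 at least 2-fold.

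**Figure D2:**
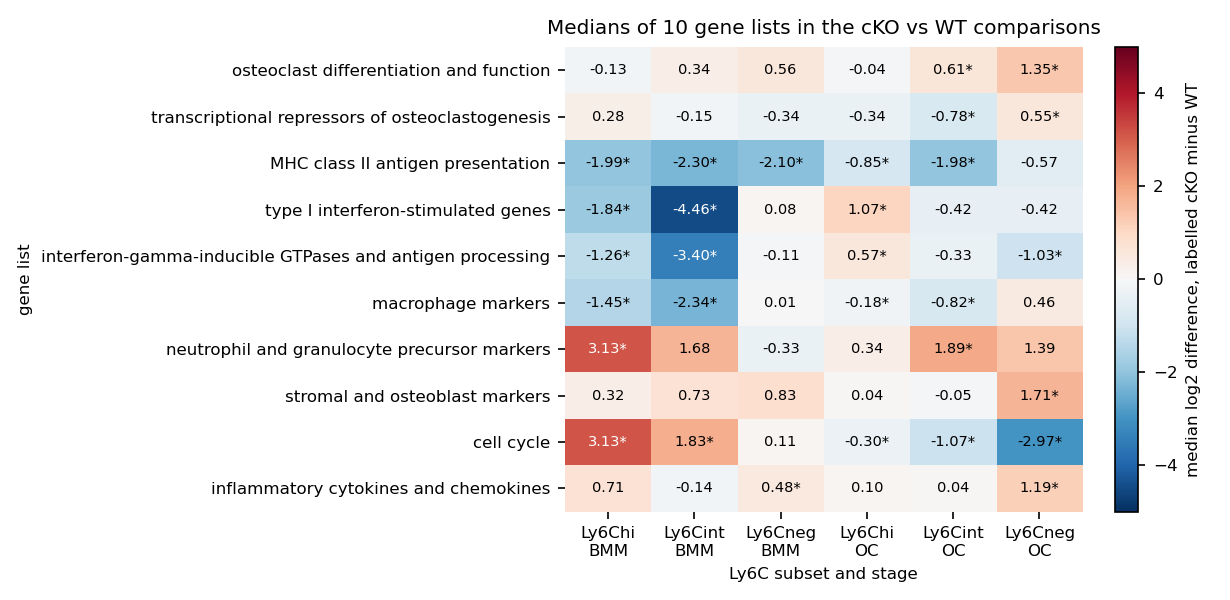
Median log2 difference, labelled cKO minus WT, of 10 gene lists (vertical axis) in the 6 combinations of Ly6C subset and stage (horizontal axis), with colour and printed value for the median and a star where the list was called with the preset and with the estimated correlation. Cell cycle medians go from 3.13 in Ly6Chi BMM to -2.97 in Ly6Cneg OC, and osteoclast medians from -0.13 to 1.35 in the same groups.

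Genes called at least 2-fold overlapped between subsets beyond the number that independent lists would share, with no library in common. At the BMM stage Ly6Chi and Ly6Cint cells shared 1308 higher genes (324.4 for independent lists, odds ratio 10.3) and 1129 lower genes (120.7, odds ratio 37.4), and Ly6Chi and Ly6Cneg cells shared 333 higher (156.1, Fisher's exact p = 4.49e-41) and 317 lower (43.6, 1.25e-190). At the OC stage Ly6Chi and Ly6Cint cells shared 225 higher (7.5, 6.46e-288) and 147 lower (5.1, 3.7e-179), and Ly6Cint and Ly6Cneg cells 349 higher (24 for independent lists, odds ratio 37.4) and 251 lower (14.1, 2.81e-253). All 3 subsets shared 241 higher and 268 lower genes in BMM and 150 higher and 71 lower in OC. In BMM, 45 genes were higher in Ly6Chi and lower in Ly6Cneg cells labelled cKO, and 60 the other way, at the same limit. Genes are not independent replicates, and sex-linked genes are among those shared.

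The stage comparisons ask how each sorted subset differs between day 0 and 4 days with RANKL. No day 4 group in MCSF alone was analysed here, so RANKL cannot be separated from the days of culture, and "with RANKL" names the 2 together. Progenitor markers fell in all 6 of these comparisons (medians -1.74 to -0.55, adjusted p = 3.7e-10 to 0.00734), and only in cKO Ly6Cint cells was the call lost with an estimated correlation (0.0572). In WT Ly6Chi cells (n = 3 and 3) the osteoclast genes rose at 23 of 24 members (median 5.09, adjusted p = 6.96e-34). Mt3, a metallothionein, rose by 7.42 ± 0.29, Ctsk from 11.21 ± 0.65 (SD) to 18.58 ± 0.03 (7.38 ± 0.39, adjusted p = 9.75e-14) and Acp5 by 7.38 ± 0.38. Akr1c18 (6.79 ± 0.22), Slc9b2 (6.71 ± 0.27) and the fusion protein gene Dcstamp (6.70 ± 0.16) followed. Monocyte and neutrophil genes fell, F13a1 (-7.61 ± 0.17), Fcrls (-7.03 ± 0.10), Ltf (-5.93 ± 0.30), Ngp (-5.77 ± 0.27) and the chemokine receptor Ccr2 (-5.71 ± 0.13). Lists that fell were neutrophil (19 of 19, -3.39, 2.58e-16), type I interferon (26 of 26, -2.43, 2.12e-23), macrophage (16 of 18 with 1 higher, -2.71, 1.23e-15) and MHC class II (10 of 11, -2.20, 5.55e-10). Classical markers (9 of 11 with 2 higher, -3.44, 1.2e-07) and the repressors of osteoclastogenesis (6 of 7, -1.57, 1.75e-06) fell too. Rising lists included cell cycle (27 of 27, 2.35, 6.19e-40), oxidative phosphorylation (19 of 19, 1.43, 1.48e-20) and V-ATPase and lysosome (15 of 22 with 6 lower, 1.03, 1.1e-06), which holds the proton pump of bone resorption. Glycolysis genes (10 of 14 with 2 lower, 0.86, 0.000821) and the mitochondrially encoded transcripts (7 of 12, 1.36, 0.000877) rose with them, with adjusted p = 0.159 and 0.252 with an estimated correlation. All these list numbers were the same when adjusted over the list alone. Calls were 5315 higher and 7923 lower, and the median of all genes went from -0.28 to -0.03 under quantile normalization. Protein-coding calls were 4582 higher and 5460 lower, and olfactory receptor genes with reads fell from 533.7 to 258.3.

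In WT Ly6Cint cells (n = 3 and 3) 22 of 24 osteoclast genes rose with RANKL (23 adjusted over the list alone, median 4.19, adjusted p = 2.19e-31). Ctsk (7.76 ± 0.39, 3.87e-14), Acp5 (7.27 ± 0.38), Akap6 (6.82 ± 0.30) and Slc9b2 (6.79 ± 0.27) rose most. The alarmin and granule genes Ltf (-8.60 ± 0.30, 1.79e-17), Ngp (-8.31 ± 0.27), Chil3 (-8.13 ± 0.27), Lcn2 (-7.47 ± 0.22) and S100a9 (-7.47 ± 0.29) fell most, and Ly6c2 fell by 6.99 ± 0.19. All 26 type I interferon genes fell (-4.23, 8.4e-40), Ifit2 among them (-6.54 ± 0.21), as did 17 of 17 interferon-gamma genes (-2.58, 1.52e-21), 19 of 19 neutrophil genes (-4.85, 2.63e-27) and 11 of 11 MHC class II genes (-1.81, 1.74e-10). Cell cycle genes rose at 26 of 27 (1.17, 4.3e-23) and oxidative phosphorylation genes at 19 of 19 (1.34, 1.58e-19). The mitochondrially encoded transcripts, the RNA quality list, rose beside them at 7 of 12 (1.71, 0.000337, adjusted p = 0.216 with an estimated correlation). Inflammatory cytokines fell at 15 of 19 with 1 higher (2 adjusted over the list alone, -1.62, 1.07e-09), Il1b (-4.58 ± 0.33). Calls were 5077 higher and 5974 lower, and quantile normalization moved the median of all genes from -0.06 to 0.07.

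In WT Ly6Cneg cells (n = 2 and 2) 22 of 24 osteoclast genes rose with RANKL (median 1.89, adjusted p = 3.92e-39). The kinase Src rose by 5.11 ± 0.32, Mmp9 by 4.99 ± 0.36, Cav1 by 4.95 ± 0.12, Cd207 by 4.87 ± 0.15 and Acp5 by 4.11 ± 0.47. Arg1 fell from 15.57 to 7.28 (-8.29 ± 0.31), followed by Mpo (-7.33 ± 0.45), Mgl2 (-7.28 ± 0.19), Rnase2a (-6.92 ± 0.24), Elane (-6.32 ± 0.52), Prtn3 (-6.29 ± 0.42) and Prss34 (-6.21 ± 0.57). Here type I interferon genes rose at 20 of 26 (21 higher and 1 lower adjusted over the list alone, median 1.11, 1.99e-21), led by Oasl2 (2.92 ± 0.32) and Oas2 (2.83 ± 0.19). Classical markers fell at 10 of 11 (-3.79, 1.54e-25), mast cell, basophil and eosinophil markers at 8 of 9 (9 adjusted over the list alone, -2.53, 6.77e-13) and glycolysis genes at 12 of 14 (-0.78, 1.36e-12). Cell cycle genes went both ways, 5 higher and 5 lower of 27 (-0.08, adjusted p = 0.431), and no mitochondrially encoded transcript was called (0.11, 0.698). Calls were 2547 higher and 2211 lower, and numbered 7570 with sample weights.

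In Ly6Chi cells labelled cKO (n = 3 and 3), osteoclast genes rose at 24 of 24 (median 4.77, adjusted p = 4.94e-38), with Acp5 at 6.24 ± 0.38, Ctsk at 6.13 ± 0.39, Mmp14 at 6.09 ± 0.25 and Src at 6.04 ± 0.26. Neutrophil genes fell at 19 of 19 (-5.28, 4.99e-26), with Camp at -8.59 ± 0.34, Ltf at -8.50 ± 0.30, Ngp at -8.44 ± 0.27 and Lcn2 at -8.25 ± 0.22. Cell cycle genes, which rose in WT, fell at 25 of 27 (26 adjusted over the list alone, -1.12, 8.2e-18). Type I interferon genes rose at 11 of 26 (12 adjusted over the list alone) and fell at 1 (0.24, 0.00683, adjusted p = 0.548 with an estimated correlation). In Ly6Cint cells labelled cKO (n = 3 and 3), 24 of 24 osteoclast genes likewise rose (5.15, 3.77e-35), with Acp5 at 6.32 ± 0.38 and Mmp14 at 6.31 ± 0.25. There 27 of 27 cell cycle genes (-1.88, 2.16e-22) and 19 of 19 neutrophil genes (-5.62, 1.81e-20) fell, with Camp at -7.35 ± 0.34 and Elane at -6.91 ± 0.42. Their type I interferon genes went both ways, 3 higher and 9 lower of 26 (-0.19, adjusted p = 0.756). The mitochondrially encoded transcripts rose at 5 of 12 in these Ly6Chi cells (0.95, 0.00562) and 7 of 12 in Ly6Cint cells (1.76, 0.000228), with adjusted p = 0.35 and 0.201 with an estimated correlation. Of the 16241 calls in Ly6Chi cells (10431 with only the compared libraries) 37.1% were higher, against 49% under quantile normalization, which moved the median of all genes from -0.27 to 0.01, and of 18928 in Ly6Cint cells 33.6%, against 48.4% (median -0.34 to -0.02). Protein-coding calls were 5029 higher and 6430 lower in Ly6Chi, and 5254 higher and 7180 lower in Ly6Cint cells. Olfactory receptor genes with reads fell from 464.7 to 110.3 in Ly6Chi and from 543.7 to 131.7 in Ly6Cint cells.

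In Ly6Cneg cells labelled cKO (n = 3 and 3) 24 of 24 osteoclast genes rose (median 3.47, adjusted p = 9.88e-42), Acp5 by 5.03 ± 0.38, Mmp14 by 4.90 ± 0.25, Itgb3 by 4.68 ± 0.24 and Ctsk by 4.66 ± 0.39. The granule enzyme genes Mpo (-6.59 ± 0.37), Elane (-5.94 ± 0.42), Prtn3 (-5.55 ± 0.35) and Ctsg (-5.45 ± 0.28) fell, as did 27 of 27 cell cycle genes (-3.00, 1.55e-44). V-ATPase and lysosome genes rose at 21 of 22 (0.85, 1.63e-17), macrophage markers at 11 of 18 (12 adjusted over the list alone) with 2 lower (0.51, 0.000104) and immediate early genes at 8 of 12 (9 adjusted over the list alone, 0.71, 4.05e-08). The stromal and osteoblast markers rose at 6 of 11 (0.88, 0.000297, adjusted p = 0.0611 with an estimated correlation). Oxidative phosphorylation genes, 6 higher (7 adjusted over the list alone) and 2 lower of 19, had a median of 0.16 that turned to -0.05 under quantile normalization (adjusted p = 0.0137, and 0.501 with an estimated correlation). The mitochondrially encoded transcripts rose at 6 of 12 (1.83, 0.00088, adjusted p = 0.252 with an estimated correlation). Of the 16542 calls 34.1% were higher, against 52.3% under quantile normalization, which moved the median of all genes from -0.36 to -0.02. Protein-coding calls were 4971 higher and 5931 lower, and olfactory receptor genes with reads fell from 753.3 to 498.

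**Figure D3:**
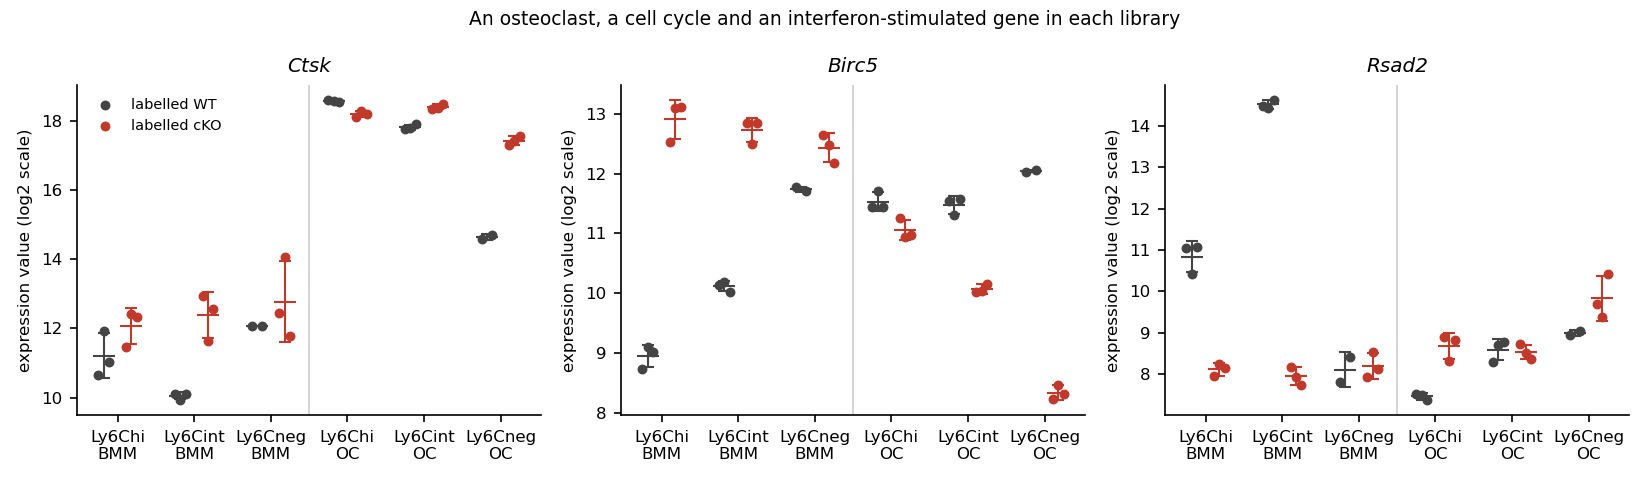
Values of the osteoclast gene Ctsk, the cell cycle gene Birc5 and the interferon-stimulated gene Rsad2 in each library on the log2 scale (vertical axes) by Ly6C subset and stage (horizontal axes), points for libraries and bars for mean ± SD, n = 3 per group and 2 in the WT Ly6Cneg groups. Ctsk means are 14.65 to 18.58 at the OC stage, Birc5 goes from 12.44 to 8.34 in Ly6Cneg cells labelled cKO, and Rsad2 is highest in WT Ly6Cint BMM (14.51).

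The subset comparisons ask how the sorted cells differ from each other within a genotype label and stage. In WT BMM, Ly6Cint cells (n = 3) had more interferon transcripts than Ly6Chi cells (n = 3), Slfn4 by 4.25 ± 0.22, Ifit2 by 4.04 ± 0.21, Acod1 by 3.96 ± 0.19 and Cxcl10 by 3.93 ± 0.17, and less Pf4 (-2.72 ± 0.23). Higher were 26 of 26 type I interferon genes (median 2.89, adjusted p = 9.67e-66), 17 of 17 interferon-gamma genes (2.15, 4.69e-42), 25 of 27 cell cycle genes (1.24, 2.11e-44) and 9 of 11 classical markers, with 1 lower (2.55, 1.72e-16). Markers of other cells moved with them, as neutrophil genes were higher at 17 of 19 (19 adjusted over the list alone, 2.01, 2.82e-26) and dendritic markers at 9 of 12 with 1 lower (0.86, 1.14e-05). Ly6c2 was 9.89 in Ly6Chi, 13.54 in Ly6Cint and 12.26 in Ly6Cneg WT BMM, so its transcript did not follow the order of the surface sort. Classical markers were also higher in Ly6Cneg than in Ly6Chi cells, at 8 of 11 with 2 lower (1.45, 8.82e-05). Ly6Cneg cells (n = 2) had far more Arg1 than Ly6Chi cells (7.56 ± 0.28, 3.01e-17), more Mpo (6.71 ± 0.41), Rnase2a (6.16 ± 0.22) and Prss34 (5.88 ± 0.52), and less Apoe (-4.77 ± 0.14), Fcrls (-4.40 ± 0.11) and Ms4a7 (-4.28 ± 0.21). Against Ly6Chi cells, 27 of 27 cell cycle genes (2.85, 3.61e-61), 8 of 9 mast cell, basophil and eosinophil markers (3.11, 8.7e-10) and 10 of 11 MHC class II genes with 1 lower (1.91, 6.86e-14) were higher. Macrophage markers were lower at 15 of 18 with 1 higher (-1.99, 6.4e-21). Against Ly6Cint cells, 26 of 26 type I interferon genes (-4.70, 1.14e-63) and 17 of 17 interferon-gamma genes (-3.37, 4.87e-36) were lower, as was Slfn4 (-7.48 ± 0.24), and Arg1 was higher by 8.50 ± 0.28. V-ATPase and lysosome genes, 2 higher and 13 lower of 22 in that comparison, had a median of -0.34 that turned to 0.11 under quantile normalization (adjusted p = 0.000356, and 0.133 with an estimated correlation). Calls were 6071 (Ly6Cint against Ly6Chi, 10355 with sample weights), 8013 (Ly6Cneg against Ly6Chi) and 8948 (Ly6Cneg against Ly6Cint), the last with a median of all genes of 0.17, and 0.04 under quantile normalization. Irf8 was lower in WT Ly6Cneg BMM than in Ly6Chi (-0.80 ± 0.09, 4.56e-09) and Ly6Cint BMM (-0.63, 7.09e-07).

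In WT OC the Ly6Cneg cells (n = 2) had lower osteoclast genes than Ly6Chi cells (n = 3) at 22 of 24 members with 1 higher (median -2.07, adjusted p = 3.86e-40) and than Ly6Cint cells (n = 3) at 22 of 24 (-1.83, 1.69e-52). Mt3 (-5.75 ± 0.33 and -4.15 ± 0.33 in these comparisons), Akr1c18 (-5.48 ± 0.25 and -3.63) and Calcr (-4.62 ± 0.27 and -3.82 ± 0.27) were lower. MHC class II genes were higher in Ly6Cneg than in Ly6Chi cells at 11 of 11 (2.48, 4.61e-24), led by H2-Eb1 (4.25 ± 0.14) and H2-Aa (4.15 ± 0.13). So were 25 of 26 type I interferon genes (26 adjusted over the list alone, 1.73, 7.29e-28). Oxidative phosphorylation genes were lower at 19 of 19 (-0.95, 4.5e-24). The mitochondrially encoded transcripts were lower too, at 5 of 12 against Ly6Chi cells (-0.90, 0.00124, and a median of -0.41 under quantile normalization) and 2 of 12 against Ly6Cint cells (3 adjusted over the list alone, -0.74, 0.000586). With an estimated correlation these had adjusted p = 0.268 and 0.235. Markers of other cells were higher in WT Ly6Cneg OC, as was the mean number of olfactory receptor genes with reads (609, against 258.3 in Ly6Chi and 183 in Ly6Cint OC). Stromal and osteoblast markers were higher at 7 of 11 against Ly6Chi (8 adjusted over the list alone, 1.32, 0.000153) and 6 of 11 against Ly6Cint cells (1.08, 0.000215), with adjusted p = 0.0524 and 0.0561 with an estimated correlation. Dendritic markers were higher at 9 of 12 (10 adjusted over the list alone, 1.13, 5.23e-07) and 8 of 12 (9 adjusted over the list alone, 0.80, 4.32e-06). Neutrophil genes were higher at 9 of 19 (0.64, 0.000363) and 5 of 19 (8 adjusted over the list alone, 0.62, 0.000426), with adjusted p = 0.394 and 0.4 with an estimated correlation. Repressors of osteoclastogenesis were higher in Ly6Cneg cells at 6 of 7 against both subsets (0.81, 1.93e-06 and 0.63, 9.62e-07), Irf8 by 1.79 (4.71e-18) and 1.13 (4.85e-12). Siglech (2.97 ± 0.37) and Igkc (2.88 ± 0.42) led the rises over Ly6Cint cells. Ly6Cint against Ly6Chi cells differed at 1128 genes, with Axl (2.47 ± 0.10) and H2-Eb1 (2.14 ± 0.12) higher and Akr1c18 (-1.85 ± 0.22) lower. There 24 of 26 type I interferon genes (26 adjusted over the list alone, 1.04, 2.6e-61) and 9 of 11 MHC class II genes (11 adjusted over the list alone, 1.24, 6.5e-41) were higher. Ly6Cneg cells differed at 7396 genes from Ly6Chi and 5268 from Ly6Cint cells, with medians of all genes of 0.20 and 0.18 that quantile normalization moved to 0.04 and 0.00. These counts were 4688 and 2662 without WT OC Ly6Cneg replicate 2, 4844 and 2805 without replicate 1. The count of Ly6Cint against Ly6Chi cells (1128) was 745 and 750 without WT OC Ly6Cint replicates 2 and 1. It was 1922 with only the compared libraries and 3820 with sample weights, and those of Ly6Cneg cells were 12218 (against Ly6Chi) and 11299 (against Ly6Cint) with sample weights, the latter 8995 with only the compared libraries.

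In BMM labelled cKO (n = 3 per subset), Ly6Cneg cells had lower neutrophil genes than Ly6Chi cells at 14 of 19 with 2 higher (median -2.49, adjusted p = 1.8e-23) and than Ly6Cint cells at 18 of 19 (-4.14, 1.07e-39). Camp (-6.30 ± 0.34 and -6.78 ± 0.34) and Ltf (-6.01 ± 0.30 and -6.25) were lower by most in these comparisons. The immunoglobulin genes Ighg1 (4.67 ± 0.60 and 4.04 ± 0.60) and Igkc (3.57 ± 0.37 and 3.40) were higher, while the means of Igha and Ighg2b were not. Ccn2 (4.39 ± 0.43 and 3.29), a matrix protein gene, was higher too. MHC class II genes were higher at 9 of 11 (10 adjusted over the list alone, 2.12, 4.1e-15) and 8 of 11 (9 adjusted over the list alone, 1.76, 3.59e-11). Stromal and osteoblast markers were higher at 8 of 11 (9 adjusted over the list alone, 1.23, 0.000271) and at 6 of 11 with 1 lower (7 and 1 adjusted over the list alone, 0.96, 0.0114), with adjusted p = 0.0598 and 0.2 with an estimated correlation. Olfactory receptor genes with reads were more in Ly6Cneg cells as well (753.3, against 464.7 in Ly6Chi and 543.7 in Ly6Cint cells). Dendritic markers were higher at 8 of 12 with 1 lower (9 and 1 adjusted over the list alone, 0.84, 1.1e-05) and 7 of 12 (8 adjusted over the list alone, 0.85, 5.21e-05). Ly6Cint against Ly6Chi cells had 12 of 19 neutrophil genes (13 adjusted over the list alone, 1.14, 3.75e-22) higher and 11 of 18 macrophage markers lower with 1 higher (13 and 1 adjusted over the list alone, -0.56, 2.57e-13). Il1b (3.31 ± 0.33, adjusted p = 5.42e-07) and Elane (2.97 ± 0.42, 6.7e-05) led its 2654 calls, which fell to 1126 with sample weights and to 0 in limma with only the compared libraries, where 3737 genes had an unadjusted p under 0.05 and Il1b an adjusted p of 0.122. In the fit of all libraries the mitochondrially encoded transcripts were lower as a list in Ly6Cint than in Ly6Chi cells, with 0 of 12 called (-0.43, 0.0347, adjusted p = 0.48 with an estimated correlation). Ly6Cneg against Ly6Chi cells gave 10513 calls, 69.6% higher and 56% under quantile normalization (median of all genes 0.24 to 0.03), and Ly6Cneg against Ly6Cint cells 10693 (0.17 to 0.03). With only the compared libraries these counts fell to 2121 and 5213, and the first to 4736 with sample weights. Cell cycle genes, 0 higher and 5 lower of 27 in Ly6Cneg against Ly6Chi cells (4 lower adjusted over the list alone), had a median of -0.09 that turned to 0.02 under quantile normalization (adjusted p = 0.000453, and 0.282 with an estimated correlation).

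In OC labelled cKO (n = 3 per subset), Ly6Cneg cells had far more of the matrix genes Col1a1, Col1a2 and Sparc than the other subsets. Col1a1 was higher than in Ly6Chi cells by 8.10 ± 0.38 (13.06 against 4.96, adjusted p = 1.71e-14) and than in Ly6Cint cells by 6.88 ± 0.38, Col1a2 by 7.28 ± 0.27 and 7.25 ± 0.27, and Sparc by 6.44 ± 0.32 and 7.14 ± 0.32. Stromal and osteoblast markers were higher at 9 of 11 in both comparisons (10 adjusted over the list alone, 3.11, 2.29e-11 and 3.08, 2.55e-10). Their medians were 1.32 and 1.08 in the same comparisons of WT OC and 1.23 and 0.96 in BMM labelled cKO. Olfactory receptor genes with reads numbered 498 in Ly6Cneg, 110.3 in Ly6Chi and 131.7 in Ly6Cint OC labelled cKO. Neutrophil genes were higher than in Ly6Chi cells at 12 of 19 (2.13, 1.3e-11, adjusted p = 0.0856 with an estimated correlation). Osteoclast genes were lower in Ly6Cneg cells at 15 of 24 with 2 higher against Ly6Chi (-0.65, 3.33e-10) and 20 of 24 (22 adjusted over the list alone) with 2 higher against Ly6Cint cells (-1.10, 3.7e-16). All 7 repressors of osteoclastogenesis were higher in both (1.49, 2.48e-12 and 1.63, 1.03e-14), Irf8 by 1.49 and 1.63. Cell cycle genes were lower at 26 of 27 (1 higher adjusted over the list alone, -1.98, 2.29e-55) and 22 of 27 with 2 higher (-1.29, 1.01e-26), with Ube2c at -2.89 ± 0.10 against Ly6Chi cells. Against Ly6Cint cells 4 of 12 mitochondrially encoded transcripts were lower (median -0.44, mean 0.23, 0.0434, adjusted p = 0.495 with an estimated correlation). The pseudogene Rps23-ps2 headed the falls against Ly6Chi cells (-3.45 ± 1.17, 0.0337) but was not called without cKO OC Ly6Chi replicate 1 (-3.27, 0.093) or 2 (-2.87, 0.143) or any of the 3 cKO OC Ly6Cneg libraries (0.0722 to 0.0775). Ly6Cint cells exceeded Ly6Chi cells in 16 of 19 neutrophil genes (19 adjusted over the list alone, 1.72, 1.99e-52), Ltf by 3.56 ± 0.30, S100a9 by 3.55 ± 0.29 and Lcn2 by 3.45 ± 0.22. They also had 9 of 24 osteoclast genes higher (12 adjusted over the list alone, 0.43, 5.49e-12), and Folr2 (-1.94 ± 0.12) and Cd207 (-1.88 ± 0.12) lower. Calls were 2047, 9138 and 9598 for Ly6Cint against Ly6Chi, Ly6Cneg against Ly6Chi and Ly6Cneg against Ly6Cint, and the first was 1177 with only the compared libraries and 4523 with sample weights. The second had 61.4% higher (51.7% under quantile normalization), with medians of all genes of 0.17 to -0.01 and, for the last, 0.14 to 0.01.

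The genotype by RANKL interactions ask whether the change from BMM to OC differs between the labels. In Ly6Chi cells it differed at 9240 genes. In libraries labelled cKO it was more positive for Kcnj10 (5.66 ± 0.24, adjusted p = 3.87e-19), Tmem176b (5.55 ± 0.18) and Tmem176a (5.50 ± 0.17). It was more negative for Ccl2 (-5.42 ± 0.23, 9.43e-18), Ccl7 (-4.73 ± 0.32), Pclaf (-4.68 ± 0.12) and Birc5 (-4.44 ± 0.18). Gvin1, with the largest value (6.34 ± 1.89, 0.0148), was not called without WT BMM Ly6Chi replicate 1 (4.82, 0.0619) or cKO OC Ly6Chi replicate 2 (5.26, 0.0561), nor with only the compared libraries or with sample weights. Irf8 changed less with RANKL in these cKO libraries (1.2 ± 0.12, 8.36e-11), and the interaction was not called in Ly6Cint (0.21, 0.183) or Ly6Cneg cells (0.31, 0.102). In Ly6Cint cells 10119 genes differed, led by Rsad2 (6.50 ± 0.32, 1.54e-14), Adgre4 (6.39 ± 0.19) and Ifit3 (6.20 ± 0.38) and by Npy (-4.93 ± 0.21), Pdpn (-4.50 ± 0.44) and Ccl2 (-4.45 ± 0.23). In Ly6Cneg cells 6721 differed, with Ear2 (5.14 ± 0.66), Mgl2 (5.11 ± 0.24) and Rnase2a (5.07 ± 0.31) more positive and Birc5 (-4.41 ± 0.20), Ube2c (-4.36 ± 0.15) and Stmn1 (-4.28 ± 0.43) more negative. The integrin Itgb3 (3.17 ± 0.37) was more positive there too. The pseudogene Rpl31-ps11 had the largest value in Ly6Cneg cells (7.23 ± 2.29, 0.0309) but was not called without WT BMM Ly6Cneg replicate 1 (0.0996) or 2 (0.0674), WT OC Ly6Cneg replicate 2 (4.21, 0.275), cKO BMM Ly6Cneg replicate 2 (0.0596), or cKO OC Ly6Cneg replicate 2 (0.0553) or 3 (0.0519). Quantile normalization moved the median of all genes from -0.24 to -0.05 in Ly6Cint and from -0.27 to -0.02 in Ly6Cneg cells.

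The genotype by subset interactions ask whether the cKO against WT difference depends on the Ly6C subset. An F test with 3 subsets called 8090 genes in BMM and 5200 in OC. With only the compared libraries these were 5003 and 8185, and the latter 8834 with sample weights. Arg1 was called in BMM (adjusted p = 3.03e-11) and not in OC (0.974). The osteoclast genes Acp5 (0.326 in BMM, 0.000832 in OC) and Akr1c18 (0.471 and 2.29e-09) and the proton pump subunit Atp6v1b2 (0.0591 and 3.34e-12) were called in OC and not in BMM. Adgre4 (3.13e-22 and 2.02e-07) and Apoe (3.36e-12 and 7.61e-09) were called at both stages.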

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

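The splits of the libraries were counted only after the real results were seen.

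The genotype by RANKL interaction differed from 0 at 9240 genes in Ly6Chi cells, 10119 in Ly6Cint cells and 6721 in Ly6Cneg cells, so in many genes the change from BMM to OC was not the same under both genotype labels. In Ly6Chi cells the largest positive and largest negative values of named genes were Gvin1 (6.34), which rests on WT BMM Ly6Chi replicate 1 (4.82 without it, adjusted p = 0.0619) and cKO OC Ly6Chi replicate 2 (5.26, 0.0561), and Ccl2 (-5.42). In Ly6Cint cells the largest positive and largest negative were Rsad2 (6.50) and Npy (-4.93). In Ly6Cneg cells they were, in the same order, Rpl31-ps11 (7.23), whose call was lost without any of 6 libraries (4.21 without WT OC Ly6Cneg replicate 2), and Birc5 (-4.41). The cKO against WT difference also depended on the Ly6C subset at 8090 genes in BMM and 5200 in OC.

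When the libraries were dealt over all 4 groups of the Ly6Chi interaction, 5 of 100 splits gave as many genes, the real one included, and the highest other split gave 12255 against the real 9240. For the Ly6Cint interaction 1 of 100 did, the real one (10119, highest other 9268). These splits stand for no difference of any kind between the groups, so they decide nothing about chance in an interaction. Chance among residuals was therefore counted after the additive fit of stage and genotype was removed, and the residuals were dealt over the 12 libraries. As many genes came in 1 of 100 splits for Ly6Chi (the real one, highest other 5260) and in 2 of 100 for Ly6Cint, where another split gave 10787 against the real 10119. Both shares are under 0.05, but the test was chosen after the first splits were seen, and the Ly6Cint count was not the largest. It deals libraries, whose replicates may be technical, so it does not exclude chance between animals or cultures.

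For groups of 3 against 3 the 10 possible splits are too few for a share under 0.05, and in each comparison 1 of 10, the real one, reached the real count. For cKO against WT the real count and the highest other were 11563 and 1371 (Ly6Chi BMM), 15414 and 3 (Ly6Cint BMM), 3056 and 2 (Ly6Chi OC) and 5490 and 0 (Ly6Cint OC). For OC against BMM they were 13238 and 1 (WT Ly6Chi), 11051 and 1 (WT Ly6Cint), 16241 and 1065 (cKO Ly6Chi), 18928 and 0 (cKO Ly6Cint) and 16542 and 54 (cKO Ly6Cneg). Between WT subsets, Ly6Cint against Ly6Chi, they were 6071 and 51 in BMM and 1128 and 3 in OC. Between cKO subsets they were 2654 and 767, 10513 and 2678, and 10693 and 1005 in BMM, and 2047 and 1, 9138 and 0, and 9598 and 0 in OC, in the order Ly6Cint against Ly6Chi, Ly6Cneg against Ly6Chi and Ly6Cneg against Ly6Cint. Groups of 2 were not split.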

How the results depend on the processing

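The 3 filters added after the data were seen (at least 10 reads, protein-coding genes, no X or Y) were not planned, and the count model and pseudocounts that were planned did not apply. Of 2409 results for named genes, none reversed under any alternative that kept the gene, but they were picked as called in these data, so reversals were unlikely. The filters kept 2399 (stricter), 2374 (at least 10 reads), 2380 (protein-coding) and 2347 (no X or Y) of them. Calls were lost in 1015 of 15104 fits with a library left out, 301 with only the compared libraries, 148 under quantile normalization, 78 with sample weights and 62 without the trended and robust prior. Among the results kept, no call was lost with no filter, the stricter filter, the 3 added filters or median-of-ratios rescaling. That rescaling moved each library by at most 0.01 and so tests little. Counts of called genes stayed within 1.5 times under every filter, quantile normalization and no prior. Of 336 called list medians 3 turned under quantile normalization. Overlaps at a log2 difference of at least 1 exceeded those of independent lists in 12 of 12 pairs, an excess that the shared fit and the genes of few reads favour. Depth limits genes of few reads, whose differences are understated. The main fit pooled 1 spread per gene over all groups, but the groups differed in spread. Sample weights were 0.32 to 1.04 in BMM labelled cKO and 1.19 to 2.19 in WT OC. Standard errors and p-values of the main fit may therefore be too small between subsets of the first and too large between those of the second. Whether this accounts for the differences below was not tested.

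With only the compared libraries the calls were 7446 (cKO against WT, Ly6Chi BMM), 4982 (Ly6Cneg BMM), 10431 (OC against BMM, cKO Ly6Chi), 1922 (Ly6Cint against Ly6Chi, WT OC), and 8995 (Ly6Cneg against Ly6Cint, WT OC). They were 2121 and 5213 (Ly6Cneg against Ly6Chi and Ly6Cint, cKO BMM), 1177 (Ly6Cint against Ly6Chi, cKO OC), and 5003 and 8185 (genotype by subset, BMM and OC). For Ly6Cint against Ly6Chi in cKO BMM limma called 0 (3737 at an unadjusted p under 0.05), against 2654 in the fit of all libraries and 1126 with sample weights. Other calls with sample weights were 6535 and 9034 (cKO against WT, Ly6Chi and Ly6Cint OC), 7570 (OC against BMM, WT Ly6Cneg) and 10355 (Ly6Cint against Ly6Chi, WT BMM, 43.4% higher against 54.6%). They were 3820, 12218 and 11299 (WT OC, Ly6Cint against Ly6Chi, Ly6Cneg against Ly6Chi and Ly6Cneg against Ly6Cint), 4736 (Ly6Cneg against Ly6Chi, cKO BMM), 4523 (Ly6Cint against Ly6Chi, cKO OC) and 8834 (genotype by subset, OC).

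With a library left out, calls ranged from 4573 to 11171 (cKO against WT, Ly6Cneg BMM), 745 to 913, 4688 to 6685 and 2662 to 4131 (WT OC, Ly6Cint against Ly6Chi, Ly6Cneg against Ly6Chi, Ly6Cneg against Ly6Cint). The lowest came without WT BMM Ly6Cneg replicate 2, WT OC Ly6Cint replicate 2 and, for the last pair, WT OC Ly6Cneg replicate 2. The interferon-gamma median of cKO against WT in Ly6Cneg BMM ranged from -0.19 to 0.02, turning without cKO BMM Ly6Cneg replicate 3. The cell cycle median of Ly6Cint against Ly6Chi in cKO BMM ranged from -0.09 to 0.01, turning without cKO BMM Ly6Chi replicate 1.

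With an estimated correlation, the number of 24 comparisons in which a list was called fell from 20 to 11 (type I interferon), 20 to 12 (neutrophil), 3 to 1 (erythroid and megakaryocyte), and 14 to 7 (progenitor). These numbers fell from 8 to 3 (stromal and osteoblast), 21 to 9 (oxidative phosphorylation), 14 to 3 (glycolysis), and 19 to 11 (V-ATPase and lysosome). They fell from 13 to 7 (immediate early) and 9 to 0 (mitochondrially encoded, camera in limma, lowest unadjusted p = 0.102). The first principal component held 35.2% of variance, and 37.7% with the stricter filter, 31.5% after quantile normalization, 42.5% with at least 10 reads and 41.4% with protein-coding genes.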

Other observations

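The tests of scaling, wrong labels, exons, a single library and depth below were chosen only after the result was seen, while the tests of further stromal genes and of further silent families were written before theirs.

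Single progenitor genes differed in Ly6Chi BMM labelled cKO, where Myb (2.48 ± 0.37) and Erg (2.23) were higher and Sox4 (-1.16) was lower (n = 3 and 3), while the progenitor list was not called (adjusted p = 0.611). In the same comparison the T cell receptor chain gene Cd3d was 3.22 ± 0.30 higher, although the T and NK cell list was not called in any of the 24 list comparisons, nor was the B cell list. Of 14 non-classical monocyte genes 5 were higher (7 adjusted over the list alone) and 3 lower in Ly6Chi OC labelled cKO (median 0.29, adjusted p = 0.00272), with the adhesion receptor Adgre4 (2.26 ± 0.14) and Cx3cr1 (1.49 ± 0.08) higher, and the sialic acid receptor Siglec1 was 2.22 ± 0.31 higher.

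Subset lists outside the osteoclast programme also moved. In OC labelled cKO, Ly6Cneg cells had more inflammatory cytokine transcripts than Ly6Chi cells at 14 of 19 genes (15 higher and 1 lower adjusted over the list alone, median 1.59, adjusted p = 9.5e-15). Immediate early transcripts were higher at 10 of 12 (11 higher and 1 lower adjusted over the list alone, 1.2, 1.98e-09), and 19 of 19 oxidative phosphorylation genes were lower (-0.96, 2.11e-24). In WT BMM the dendritic markers were higher in Ly6Cneg than in Ly6Chi cells at 11 of 12 with 1 lower (2.26, 3.9e-09), and V-ATPase and lysosome genes lower at 15 of 22 (16 adjusted over the list alone, -0.55, 8.57e-09).

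The Irf8 gene total was higher in libraries labelled cKO. Scaling between libraries does not account for it, since the smallest of the 6 differences under quantile normalization was 0.61 and all stayed called. As to single libraries with a wrong genotype label, 0 of 34 had Ddx3y or Irf8 within or beyond the range of the other genotype of its subset and stage. That cannot exclude them, since Irf8 is the pattern itself and Ddx3y marks sex, not the Irf8 genotype. Reads on exons left in the targeted allele remain possible, because the smallest difference (0.68) comes from a gene total without exon reads, and this cannot be told apart from a true rise or from an exchange of the labels of all libraries. The mix of sexes, which differs with the label, stays open as well and was not tested.

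Collagen and other matrix genes were high in Ly6Cneg OC labelled cKO. A single contaminated library does not account for it, since the lowest of the 3 libraries had Col1a1 4.30 above the highest WT Ly6Cneg OC library. Of 16 further stromal genes, 14 were called at least 1 higher in Ly6Cneg than in Ly6Chi OC labelled cKO, among them Col5a1 (4.95, adjusted p = 9.54e-19), Col6a1 (4.92, 3.51e-11) and Acta2 (3.70, 4.7e-19), and Dcn (0.28, 0.633) and Lum (0.32, 0.704) were not. The stromal list was also higher in Ly6Cneg than in Ly6Chi and Ly6Cint cells, by less, in WT OC (medians 1.32 and 1.08) and in BMM labelled cKO, before culture with RANKL (1.23 and 0.96), though these calls were lost with an estimated correlation. The same Ly6Cneg groups also had more olfactory receptor genes with reads (609 in WT OC and 753.3 in BMM labelled cKO, against 183 to 543.7 in the other subsets), so these smaller medians do not settle whether the signal is particular to 1 genotype label or to cultured cells. Stromal cells among the sorted or cultured cells may be a source of it, a hypothesis that the low Dcn and Lum leave incomplete. A change of expression within the sorted cells, with genotype or sex, stays open and was not tested.

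Olfactory receptor genes had reads in 702 to 798 of 910 genes in the Ly6Cneg BMM libraries labelled cKO and 75 to 160 in the Ly6Chi OC libraries labelled cKO. Depth does not account for it, since the first group had 0.94 times the relative depth of the second. Other silent families were detected more often in the same group, by ratios of 4.47 (Vmn1r), 3.79 (Vmn2r), 6.88 (Krtap) and 11 (Defb), against 6.83 for olfactory receptors. Reads from outside mature transcripts, such as genomic DNA, may therefore add to these libraries. No biological explanation was tested.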
